A study of Mus musculus with 9 samples.

How the data were processed

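RNA was sequenced from germinal center B cells sorted from mouse spleen, in 9 libraries from 3 groups of 3. Per the labels' protocols, C57BL/6 recipients received a mixture of wild-type and Foxo1(f/f) B cells in equal parts. Both kinds of cell carried the B1-8hi antigen receptor, which binds the hapten NP, and ERT2cre, a recombinase that tamoxifen switches on. The mice were immunized with NP coupled to chicken gamma globulin in alum and given tamoxifen by mouth from day 7 to day 9, and cells were sorted on day 12 as B220+ NP+ GL7+ CD38-negative cells. Wild-type cells were sorted into a light zone gate (LZ, high CD86 and low CXCR4) and a dark zone gate (DZ, low CD86 and high CXCR4). Foxo1(f/f) cells, called Foxo1-deficient here, were sorted as whole germinal center cells with no zone gate. The labels give the Foxo1(f/f) cells the genotype CD45.1/2 but a CD45.2-negative sort gate, and which of these entries holds was not settled here. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

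Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with the NEBNext Ultra kit. The submitters' processing notes name TopHat2 2.0.8, Cufflinks 2.1.1 and the mm9 build, with no role or order. Per the file headers, the authors deposited 1 Cufflinks gene table per library, with FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), the bounds of its confidence interval and a status for each gene. Which total the FPKM values were scaled to, and whether a bias correction or a ribosomal RNA mask was used, is not given in the sources used here. Coordinates are those of the files, on mm9, and the reference genome supplied with the data, which is of another build, was not used.

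Each table held 23700 entries. Left out of the tests were 716 entries of 250 symbols that occur more than once and 7 genes with a failed estimate in any library, which left 22977 genes. The test was limma with an intensity trend on log2(FPKM + 1), over the 10004 genes with an FPKM of at least 1 in at least 3 of the 9 libraries. All libraries entered 1 fit on the group means, with no replicate block. Adjusted p-values are Benjamini-Hochberg values from limma within each comparison, two-sided, with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and each is the group named first minus the group named second. A gene counted as changed against both zones had to pass against LZ and against DZ in the same direction. The same 3 Foxo1-deficient libraries enter both comparisons, so the overlap was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

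The depth is not stated, but the Cufflinks intervals allow an estimate. Taken as 2 SD of a Poisson count, they gave an estimate of the fragments of each gene, called implied fragments. In genes under 30 implied fragments, the ratio of lower to upper bound was compared with fractions of whole numbers up to 60. It matched such a fraction in 85.0% to 86.6% of these genes (tolerance 5e-06), against 0.7% to 1.6% of random numbers over the same range. On this estimate the relative depth of the libraries was 0.84 to 1.11. These are estimates, and the fragments were used only in an alternative. In 9011 genes with a median of at least 20 implied fragments, each library listed between 8 and 230 genes at exactly 0, so a 0 in these files can be a failed estimate. Genes with such values are described as listed at 0, by library, with no mean and no fold against a group at 0.

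Before the data were examined, 27 gene lists of zones, cell cycle, metabolism, signalling and other spleen cells were fixed: dark zone genes, light zone genes, S phase, G2 and M phase, somatic hypermutation and DNA repair, Myc targets and ribosome biogenesis, mTORC1 and amino acid metabolism, glycolysis, oxidative phosphorylation, sterol and lipid synthesis, NF-kB and CD40 response, B cell receptor signalling, MHC class II presentation, Foxo targets, germinal center B cell identity, plasma cell genes, naive and memory B cell markers, T cell markers, macrophage and dendritic cell markers, neutrophil markers, erythroid and platelet markers, stromal and follicular dendritic cell markers, interferon response, stress and dissociation genes, apoptosis regulators, chemokine receptors and migration, and T cell help receptors and ligands. The 24 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 72 tests, and again with an estimated correlation and with fry. Camera sets a list against all other tested genes. Counts of changed members are given over all genes and adjusted over the list alone.

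The genes named follow a rule fixed at the same time. They are Foxo1 and the sort genes Cd86, Cxcr4, Cd38 and Ptprc, and per comparison the 10 largest rises and 10 largest falls past the threshold. These needed a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups, a separation that chance gives 10% of genes when 3 libraries are set against 3. For changes against both zones the rule took the 10 largest in each direction by the smaller of the changes. Up to 4 members of each list with the smallest p were added. Predicted genes, small RNAs, antigen receptor segments and sex genes were left out by this rule. Genes named outside it are said to have been chosen after their values were seen.

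The test was tried on simulated data with the real genes and spread for the comparison of Foxo1-deficient cells with LZ. In simulations of 10004 genes it recovered 34.4% of the genes changed by log2 1 and 93.2% of those changed by log2 2. Of its calls, 5.4% were unchanged genes. The changed genes were drawn only from better expressed genes, so the shares recovered do not cover low genes. The simulated noise was independent between genes. For changes against both zones the shares recovered were 24.0% and 90.7%. Alternatives covered the pseudocount, the filter, quantile normalization and median centring, fits on the compared groups alone, the replicate number as a block, library weights, a robust spread, a fold threshold and each library left out in turn. Added after the data were seen were voom weights on the implied fragments, fits without small RNA genes or genes with a failed status, with repeated symbols kept, over genes with a wild-type mean of at least 1 FPKM or without genes listed at 0 in 1 library of a group, and lists without the sort genes. A count test was written into the plan in case the files held counts. They held FPKM, so limma was used as planned for that case. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.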

Results

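The study asks what the transcription factor Foxo1 does in germinal center B cells, in their proliferation and in the help they receive from T cells. In the germinal center, B cells divide and mutate their antibody genes in the dark zone and are selected by antigen and T cells in the light zone. The data are gene-level FPKM values of 9 RNA libraries: 3 of wild-type LZ cells, 3 of wild-type DZ cells and 3 of Foxo1-deficient cells sorted without a zone gate. Between 11229 and 12495 of the 23700 entries of each table were above 0, and the relative depth estimated from the confidence intervals ran from 0.84 to 1.11. Across the tested genes, replicates correlated at Pearson's r of 0.905 to 0.912 in LZ, 0.938 to 0.942 in DZ and 0.868 to 0.915 in Foxo1-deficient cells. Genes are not independent replicates, so these r values describe the libraries only. Unless stated otherwise, values are mean FPKM ± SD (n = 3), changes are log2 differences on the log2(FPKM + 1) scale, and adjusted p-values are from limma for genes and camera for lists.

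Foxo1, the targeted gene, lies on chromosome 3 from 52072259 to 52154031 (mm9). Its FPKM was 14.8, 18.7 and 22.1 in the 3 LZ libraries, 24.5, 19.5 and 19.1 in the 3 DZ libraries, and 3.01, 1.79 and 0.81 in the 3 Foxo1-deficient libraries. Against LZ it fell by 2.82 on the log2 scale (adjusted p = 0.00113), and against DZ it fell by 3.01 (adjusted p = 0.000542). Between the wild-type zones the change was 0.18 (adjusted p = 0.842). The value covers the whole gene, and which part is deleted is not given in the sources used here.

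The genes of the sort markers followed the gates. Cd86, a costimulatory ligand for T cells, was 51.7 ± 7.01 in LZ and 15.8 ± 2.97 in DZ, and was 56.5 ± 2.05 in Foxo1-deficient cells. It fell by 1.65 from LZ to DZ (adjusted p = 0.00151) and rose by 1.79 in Foxo1-deficient cells against DZ (adjusted p = 0.000542), while the change against LZ was 0.13 (adjusted p = 0.799). Cxcr4, the chemokine receptor that holds B cells in the dark zone, was 33.3 ± 4.48 in LZ, 72.5 ± 11.2 in DZ and 22.3 ± 4.10 in Foxo1-deficient cells. It rose by 1.10 from LZ to DZ (adjusted p = 0.019) and fell by 1.66 in Foxo1-deficient cells against DZ (adjusted p = 0.00143), with a change of -0.56 against LZ that did not pass (adjusted p = 0.218). The Cxcr4 call between zones was lost without LZ replicate 1 or 2 or DZ replicate 1 or 2, with a highest adjusted p of 0.0854. Ptprc, which encodes the CD45 alleles that mark the donors, was 167 ± 11.5 in LZ, 112 ± 8.69 in DZ and 213 ± 9.31 in Foxo1-deficient cells, and rose by 0.92 against DZ (adjusted p = 0.00291). Its fall from LZ to DZ (-0.58, adjusted p = 0.0433) was lost under median centring, with the replicate number as a block, with only the compared groups in the fit, and without any 1 library other than Foxo1-deficient replicate 3, with adjusted p up to 0.156. Cd38, low on sorted germinal center cells, was 5.90 ± 1.71, 2.70 ± 0.182 and 3.11 ± 1.88 and passed in no comparison (adjusted p from 0.281 to 0.962).

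**Figure D1:**
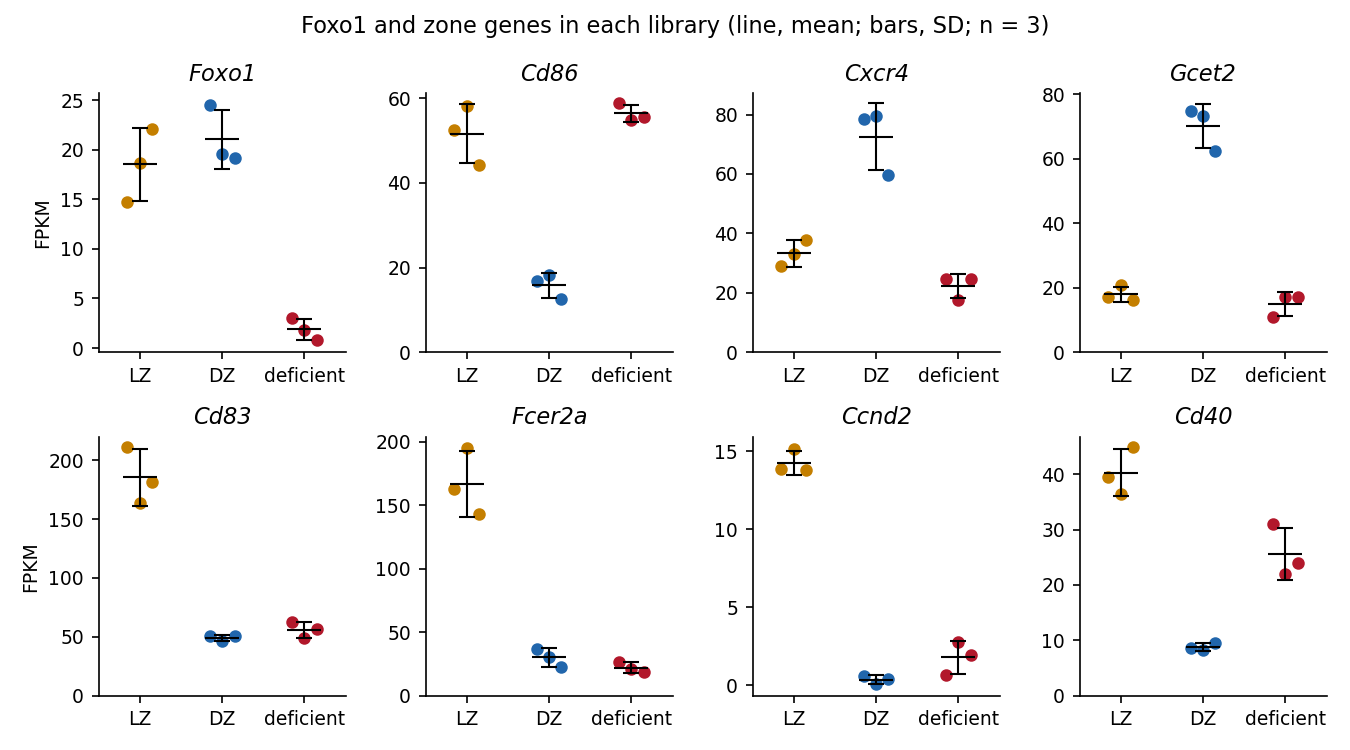
FPKM (y axis, linear, its own scale for each gene) of Foxo1 and 7 zone genes, with a point for each library, a line for the mean and bars for the SD (n = 3). Foxo1 lies at 0.81 to 3.01 in the Foxo1-deficient libraries and at 14.8 to 24.5 in the wild-type libraries.

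The DZ and LZ libraries show how the zones differ in cells with Foxo1. In DZ, Gcet2, a signalling adaptor of germinal center B cells, was 70.1 ± 6.79 against 18.0 ± 2.38 in LZ and rose by 1.91 (adjusted p = 0.00151). Polh, the error-prone polymerase of somatic hypermutation, rose from 14.3 ± 2.72 to 41.1 ± 6.46 (1.46, adjusted p = 0.0059). Ccnd2, a D-type cyclin, was 14.3 ± 0.77 in LZ against 0.363 ± 0.266 in DZ and fell by 3.50 (adjusted p = 0.000878). Cd40, the receptor for a T cell help signal, was 40.3 ± 4.27 against 8.77 ± 0.709 and fell by 2.08 (adjusted p = 0.00061). Of 10004 genes tested, 194 differed, 56 higher in DZ and 138 lower, and 1542 had an unadjusted p under 0.05.

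Other large rises in DZ included Pafah1b3, a subunit of an acetylhydrolase of platelet-activating factor (2.51), the deubiquitinase Otub2 (1.72), Serinc5 (1.67), Anxa2, a calcium-dependent phospholipid-binding protein (1.57), selenoprotein P gene Sepp1 (1.75), the kinase-associated phosphatase gene Cdkn3 (1.79) and the biliverdin reductase Blvrb (1.56). Anxa2 was 93.6 ± 5.37 in DZ against 31.0 ± 4.37 in LZ, and Pafah1b3 75.0 ± 13.8 against 15.1 ± 10.0. Tifa, an adaptor of TRAF6, was 5.23 ± 0.574 against 0.682 ± 0.394. Tmsb15b2, of the thymosin family, was under 0.01 in the 3 LZ libraries, 2 of them listed at 0, and at 2.08, 5.24 and 10.0 in DZ. Large falls besides that of Ccnd2 were of Il4i1, a secreted amino acid oxidase (77.5 ± 17.6 in LZ, 5.43 ± 4.91 in DZ, -3.89), Ppap2a (-2.53), the low-affinity IgE receptor Fcer2a (167 ± 26.1 against 30.2 ± 7.22, -2.44), Grm6 (-2.41), the complement factor Cfp (-2.36), Ubxn11 (-2.36) and Ccdc17 (-2.33). Bcl2a1d, an inhibitor of apoptosis, was 49.2 ± 9.00 in LZ and 9.09 ± 1.54 in DZ (-2.31), and its near-identical copies Bcl2a1a (-2.13) and Bcl2a1b (-2.31) share sequence with it, so their separate values are uncertain. Ccl22, a chemokine that draws T cells, was 7.20, 8.85 and 3.70 in LZ and 0.41, 0 and 0 in DZ. Adjusted p for these genes ran from 0.00061 (Fcer2a) to 0.042 (Blvrb). The naming rule required that the libraries of the groups not overlap, which chance gives 10% of genes, so the lack of overlap adds no support.

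Of 24 light zone genes fixed before the data were examined, 12 fell and 0 rose in DZ (19 fell adjusted over the list alone), with a median of -1.42 (adjusted p = 3.39e-20, and adjusted p = 0.0381 with an estimated correlation). Cd83, a membrane protein of activated B cells, was 185 ± 24.2 in LZ and 49.3 ± 2.46 in DZ (-1.88), and the list's Cd86, Cd40 and Ccnd2 are described above. Of 12 dark zone genes, 3 rose and 0 fell (6 rose adjusted over the list alone; Gcet2, Polh and Cxcr4 over all genes), with a median of 0.53 (adjusted p = 1.41e-09, but adjusted p = 0.0631 with an estimated correlation). Cd86 and Cxcr4 belong to these lists and were used for the sort. Without the 4 sort genes, a check added after the data were seen, the set tests gave the same 43 calls over the 3 comparisons.

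Genes of mitosis stood higher in DZ. Of 30 genes of G2 and M phase, 7 rose and 0 fell (18 rose adjusted over the list alone), the median was 0.56, and all 30 changes were positive (adjusted p = 1.83e-22, and adjusted p = 0.0381 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, was 56.1 ± 13.0 against 26.3 ± 3.50, Cenpa, the centromeric histone, 36.8 ± 4.88 against 16.2 ± 4.58, and Nuf2, of the kinetochore, 33.1 ± 2.24 against 17.2 ± 2.73. Cdca8, of the chromosomal passenger complex, rose by 1.08. Of 26 S phase genes none passed over all genes or over the list alone, yet their median of 0.16 was above that of other genes (adjusted p = 0.000165, but adjusted p = 0.311 with an estimated correlation). Pola1, the catalytic subunit of DNA polymerase alpha, was 23.8 ± 1.89 in DZ and 16.3 ± 1.99 in LZ (0.52, adjusted p = 0.174). Of 22 hypermutation and repair genes 1 rose, Polh (4 rose and 1 fell adjusted over the list alone), with a median of 0.06 (adjusted p = 0.0136, but adjusted p = 0.201 with an estimated correlation).

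Lists of signalling and presentation genes were tested next. Of 24 NF-kB and CD40 response genes, 11 fell and 0 rose in DZ (17 fell adjusted over the list alone), with a median of -0.98 (adjusted p = 2.02e-16, and adjusted p = 0.0381 with an estimated correlation). Nfkb2, a subunit of the alternative NF-kB pathway, was 35.6 ± 2.62 in LZ and 14.5 ± 2.81 in DZ. Of 15 genes of MHC class II presentation, 10 fell and 0 rose (13 fell adjusted over the list alone), with a median of -0.80 (adjusted p = 1.79e-12, but adjusted p = 0.101 with an estimated correlation). H2-Aa, a chain of the class II molecule, was 1206 ± 109.7 in LZ and 665 ± 46.6 in DZ, H2-DMb1, of the peptide-loading complex, 137 ± 1.55 and 68.8 ± 12.3, and Ifi30, a lysosomal thiol reductase, 229 ± 22.9 and 83.1 ± 11.6. Of 17 T cell help receptors and ligands, 6 fell and 0 rose (8 fell adjusted over the list alone), with a median of -0.70 (adjusted p = 5.38e-06, but adjusted p = 0.101 with an estimated correlation). These included Tnfrsf14 (22.4 ± 5.23 in LZ, 5.15 ± 0.874 in DZ), a receptor of the TNF family, and Slamf1 (29.3 ± 5.27 and 10.2 ± 0.840), a homotypic receptor on B and T cells. Of 23 B cell receptor signalling genes, 3 fell and 0 rose (5 fell adjusted over the list alone), with a median of -0.18 that became 0.01 under median centring (adjusted p = 0.0135, but adjusted p = 0.474 with an estimated correlation). They included Cr2, a complement receptor, and Cd22, an inhibitory coreceptor, which fell by 1.43 and 1.17. The B cell receptor signalling call was lost without LZ replicate 1 (adjusted p = 0.0501).

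Metabolic lists were tested as well. Of 30 Myc targets and ribosome biogenesis genes, 4 fell and 0 rose in DZ (20 fell adjusted over the list alone), with a median of -0.68 (adjusted p = 1.09e-11, but adjusted p = 0.0944 with an estimated correlation). Myc, the growth regulator itself, was 23.7 ± 2.26 in LZ and 6.38 ± 1.88 in DZ (-1.77, adjusted p = 0.00641), and the nucleolar genes Nop56, Mybbp1a and Ncl fell by 1.07, 0.95 and 0.75. Of 22 sterol and lipid synthesis genes none passed over all genes (1 fell adjusted over the list alone), and all 22 changes were negative, with a median of -0.49 (adjusted p = 3.4e-05, but adjusted p = 0.0944 with an estimated correlation). No gene of the 19 glycolysis genes (7 fell adjusted over the list alone) or the 17 mTORC1 and amino acid genes (2 fell adjusted over the list alone) passed over all genes. Their medians were -0.36 (adjusted p = 0.0044) and -0.42 (adjusted p = 0.011), and with an estimated correlation adjusted p = 0.327 and adjusted p = 0.415. The 25 oxidative phosphorylation genes held no gene that passed either way, and their median of 0.08 stood above other genes (adjusted p = 0.0245, but adjusted p = 0.443 with an estimated correlation). The mTORC1 call was lost without LZ replicate 3 (adjusted p = 0.101), and the oxidative phosphorylation call under quantile normalization (0.0760) and without LZ replicate 2 (0.0901), DZ replicate 1 (0.147) or DZ replicate 2 (0.0505).

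The all-gene median of the change from LZ to DZ was -0.146, and it became 0.008 under quantile normalization and 0.043 under median centring. With it the share of higher genes among the calls went from 28.9% to 42.8% and 56.8%. Relative to these shifts the light zone median was -1.25 and -1.23 and that of G2 and M phase 0.67 and 0.75. The count of 194 became 90, 73 and 85 without LZ replicates 1, 2 and 3, 73, 79 and 76 without DZ replicates 1, 2 and 3, 109 with no filter, 122 with only the compared groups in the fit and 331 with voom weights on the implied fragments, which kept 153 of the 194. The 56 higher and 138 lower genes became 10 and 63 without DZ replicate 1, 10 and 69 without DZ replicate 2, and 144 and 187 with voom weights. Of 51 calls followed gene by gene, 24 were kept without each of the 9 libraries, among them those of Gcet2, Anxa2, Otub2, Polh, Cd83, Cd40, Ccnd2, Fcer2a, Myc, Nfkb2, Cr2, Cd22, Ifi30, H2-Aa, S1pr3 and Tnfrsf14. Voom weights lost the calls of Tnfrsf14, Ppap2a, Bcl2a1a, Tmsb15b2, Tifa, Cdkn3, Ccl22, Cfp, Ubxn11 and Ccdc17, and no filter that of Il4i1. Calls kept in at most 4 of the 9 fits without 1 library included those of Tmsb15b2, Tifa, Cdkn3, Blvrb, Cfp, Ccdc17, Cdc20, Nuf2, Cenpa, Mybbp1a, Nop56, Ncl, Igj and Slamf1, and that of Blvrb was also lost with the replicate number as a block. Without LZ replicates 1, 2 and 3, 21, 21 and 19 of the 51 calls were lost, without DZ replicates 1, 2 and 3, 22, 20 and 20, and without Foxo1-deficient replicates 1 and 2, 2 and 3, with adjusted p up to 0.156.

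**Figure D2:**
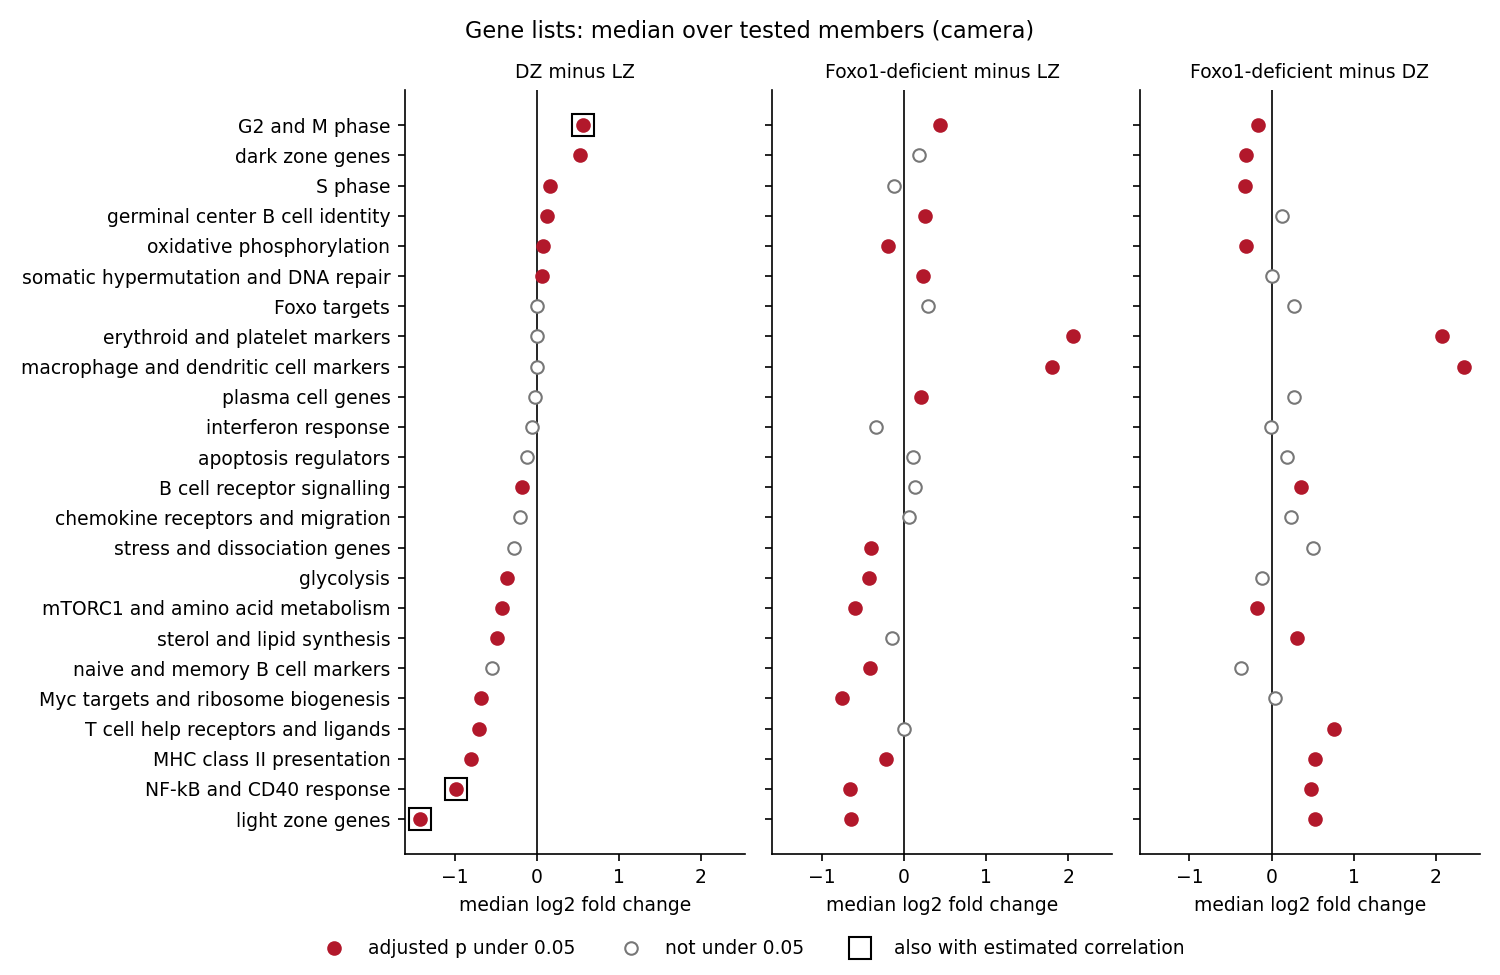
Median log2 change of each gene list (x axis, same scale in each panel) in the 3 comparisons, with filled points for lists with a camera adjusted p under 0.05 and squares for those also under it with an estimated correlation. The light zone list lies at -1.42 for DZ against LZ, at -0.65 for Foxo1-deficient cells against LZ and at 0.53 for Foxo1-deficient cells against DZ.

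Against LZ, Foxo1-deficient cells had less of several genes that were high in LZ. Wild-type cells were sequenced only by zone and Foxo1-deficient cells only without a zone gate. Genotype and gate thus change together in the comparisons with LZ and with DZ, and a difference from a single zone could come from either. So could a difference from both zones, since cells outside both zone gates could enter only the Foxo1-deficient libraries. Fcer2a was 22.0 ± 4.18 in Foxo1-deficient cells against 167 ± 26.1 in LZ and fell by 2.87 (adjusted p = 6.39e-05). Cd83 was 56.1 ± 6.79 against 185 ± 24.2 and fell by 1.71 (adjusted p = 0.000283), and Ccnd2 was 1.78 ± 1.07 against 14.3 ± 0.77 and fell by 2.54 (adjusted p = 0.00591). In all, 156 genes differed, 69 higher and 87 lower, and 1343 had an unadjusted p under 0.05.

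Other genes with large falls were Gstt1, a glutathione transferase, at 0.32, 0 and 0 in the Foxo1-deficient libraries and 9.61, 4.05 and 16.5 in LZ, its chromosome 10 neighbour Ddt, a tautomerase of the MIF family (12.6 ± 8.04 against 62.7 ± 20.3, -2.33), Tmem106c (0.812 ± 0.25 against 7.66 ± 3.43, -2.20), the glycosyltransferase B3gnt5 (0.675 ± 0.069 against 6.33 ± 2.36, -2.07), the hexose transporter gene Slc2a6 (-2.09) and Bcl2a1b (-2.12). Gcsh, of the glycine cleavage system, was 2.22, 2.44 and 0 against 7.85, 7.52 and 14.4. The largest rises were of Lyz2, a lysozyme of myeloid cells, at 51.6, 61.2 and 127 against 0.17, 0 and 0 in LZ, S100a9 at 52.5, 56.5 and 80.5, S100a8 at 21.1, 54.5 and 44.9, the adaptor gene Tyrobp at 19.3, 21.8 and 23.9 and S100a4 at 20.1, 14.6 and 25.6, the last 4 listed at 0 in the 3 LZ libraries. Further rises were of Lyz1 (6.79, 18.8 and 12.0) and the Fc receptor chain Fcer1g (4.36, 15.2 and 15.1), both listed at 0 in LZ, of Plac8 (22.0, 14.4 and 30.4 against 0, 2.29 and 0), of Slpi, a protease inhibitor (113 ± 33.6 against 7.41 ± 7.38), and of the beta-globin gene Beta-s (173 ± 129 against 12.0 ± 7.34). Lyz1 and Lyz2 are near-identical copies, as are Beta-s and Hbb-b2, so their separate values are uncertain. Adjusted p for these genes ran from 1.7e-05 to 0.0452, with no overlap between the groups' libraries, which the naming rule required.

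Lists of light zone, NF-kB and growth genes were tested against LZ. Of 24 light zone genes, 5 fell and 0 rose (13 fell and 1 rose adjusted over the list alone), with a median of -0.65 (adjusted p = 1.2e-08, but adjusted p = 0.0648 with an estimated correlation). They were Ccnd2, Cd83, Bcl2a1d (15.5 ± 3.53 against 49.2 ± 9.00) and its near-identical copies Bcl2a1a and Bcl2a1b. Of 24 NF-kB and CD40 response genes, 6 fell and 0 rose (14 fell adjusted over the list alone), with a median of -0.66 (adjusted p = 2.48e-10, but adjusted p = 0.0631 with an estimated correlation). Tnfaip3, a negative regulator of NF-kB, was 3.75 ± 0.248 against 11.2 ± 2.06, Birc3, a ubiquitin ligase of the pathway, 24.1 ± 1.34 against 45.3 ± 2.90, and Bcl2a1a fell by 1.38. Of 30 Myc targets and ribosome biogenesis genes, 3 fell and 0 rose (22 fell adjusted over the list alone), with a median of -0.76 (adjusted p = 7.41e-15, but adjusted p = 0.0648 with an estimated correlation). They were Ldha, which makes lactate (92.3 ± 17.1 against 176 ± 8.38), Hspd1, a mitochondrial chaperone (49.9 ± 5.68 against 86.2 ± 10.6), and Ncl (53.3 ± 2.96 against 89.5 ± 6.69), while Nop2 at 7.30 ± 4.31 against 20.9 ± 3.91 did not pass (adjusted p = 0.0568). In the same libraries the macrophage list had a median change of 1.80.

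Of 17 mTORC1 and amino acid genes, 2 fell and 0 rose (9 fell adjusted over the list alone), with a median of -0.60 (adjusted p = 1.34e-06, but adjusted p = 0.169 with an estimated correlation). Asns, asparagine synthetase, was 1.76 ± 0.903 against 8.49 ± 2.07 and Slc7a5, a leucine transporter, 9.08 ± 2.66 against 24.1 ± 3.26. Of 19 glycolysis genes 1 fell, Ldha (5 fell and 1 rose adjusted over the list alone), with a median of -0.42 (adjusted p = 2.56e-05, but adjusted p = 0.181 with an estimated correlation). The 25 oxidative phosphorylation genes held none that passed either way and had a median of -0.20 (adjusted p = 0.0144, but adjusted p = 0.429 with an estimated correlation), a call lost without Foxo1-deficient replicate 3 (adjusted p = 0.1004). The 30 genes of G2 and M phase held none that passed (2 rose adjusted over the list alone), and their median was 0.43 (adjusted p = 2.77e-08, but adjusted p = 0.0988 with an estimated correlation). Cenpf, a centromere protein, was 11.5 ± 0.892 against 5.63 ± 0.784 (0.91, adjusted p = 0.0629), and Mki67, a marker of cycling cells, 125 ± 3.62 against 83.3 ± 16.1 (0.59, adjusted p = 0.0941). The 26 S phase genes held none that passed and had a median of -0.12 (adjusted p = 0.161). Markers of macrophages and red cells were higher in the same Foxo1-deficient libraries, with 5 of 8 and 4 of 5 tested genes passing.

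Of 12 dark zone genes 1 rose and 2 fell (4 rose and 3 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.664). Its median was 0.18 and its mean -0.01. Polh rose (28.5 ± 2.71 against 14.3 ± 2.72, 0.96, adjusted p = 0.0391), while Rgs13, which dampens chemokine receptor signals, and the transcription factor Foxp1 fell by 0.93 and 1.43 (adjusted p = 0.0176 and 0.0373). Of 22 hypermutation and repair genes 1 rose, Polh (1 rose adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0245, but adjusted p = 0.235 with an estimated correlation). That call was lost without Foxo1-deficient replicate 3 (adjusted p = 0.0759). The 15 MHC class II genes held none that passed either way, with H2-Aa at 943 ± 108 against 1206 ± 109.7, and their median was -0.22 (adjusted p = 0.0328, but adjusted p = 0.534 with an estimated correlation). That call was lost without LZ replicate 1 (adjusted p = 0.106), LZ replicate 3 (0.0655) or Foxo1-deficient replicate 2 (0.275). The 17 T cell help genes held none that passed (4 fell and 1 rose adjusted over the list alone; adjusted p = 0.448), with a mean of -0.05 beside a median of 0.00. Of 23 B cell receptor signalling genes 1 fell, Cd72, an inhibitory coreceptor (22.7 ± 8.52 against 60.7 ± 17.3; 3 fell and 1 rose adjusted over the list alone), and the list did not pass (median 0.14, adjusted p = 0.143). The macrophage and red cell lists had medians of 1.80 and 2.05 in the same comparison.

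The count of 156 became 49, 56 and 57 without LZ replicates 1, 2 and 3, 98 and 94 without DZ replicates 1 and 2, and 97, 50 and 41 without Foxo1-deficient replicates 1, 2 and 3. It was 99 with a pseudocount of 0.1, 96 with a minimum of 5 FPKM, 58 with only the compared groups in the fit and 74 over genes with a wild-type mean of at least 1 FPKM. The balance of 69 higher and 87 lower genes was not stable. It became 19 and 78, 15 and 35, and 13 and 28 without Foxo1-deficient replicates 1, 2 and 3, where genes found only in these cells fail the filter, and 27 and 22, 33 and 23, and 29 and 28 without LZ replicates 1, 2 and 3. It was 100 and 63 with no filter and 20 and 54 over the wild-type mean of at least 1 FPKM. Of 45 calls followed gene by gene, 11 were tested and kept without each of the 9 libraries, those of S100a9, Beta-s, Hbb-b2, Fcer1g, Gstt1, Fcer2a, Ccnd2, Ddt, Cd83, Bcl2a1d and Igj. Voom weights kept 83 of the 156 calls. They lost those of Beta-s, Fcer1g and Gstt1 and of the large rises Lyz2, S100a8, S100a4, Plac8 and Lyz1, and a pseudocount of 0.1 lost those of Ccnd2 and Plac8. Calls kept in at most 4 of the 9 fits without 1 library included those of Gcsh (0 of 9), Foxp1, Polh, Hspd1, Ncl and Bach2 (1 of 9 each), Slc2a6, Birc3, Cd72, Tmem106c, Tnfaip3, Cd2, Slc7a5 and Bcl2a1a. Those of Gcsh, Birc3, Bach2 and Alas2 were also lost with the replicate number as a block, and that of Slc2a6 under quantile normalization. Without LZ replicates 1, 2 and 3, 25, 23 and 20 of the 45 calls were lost, without DZ replicates 1, 2 and 3, 10, 12 and 7, and without Foxo1-deficient replicates 1, 2 and 3, 13, 17 and 17, with adjusted p up to 0.168.

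Foxo1-deficient cells were then compared with DZ. Gcet2 was 14.97 ± 3.64 against 70.1 ± 6.79 in DZ and fell by 2.18 (adjusted p = 0.00044), and Foxp1 was 4.45 ± 2.14 against 20.5 ± 2.80 and fell by 2.04 (adjusted p = 0.00399). Cr2 was 76.5 ± 7.10 against 17.3 ± 1.72 and rose by 2.08 (adjusted p = 0.000115), Cd40 was 25.6 ± 4.72 against 8.77 ± 0.709 and rose by 1.44 (adjusted p = 0.00254), and Cd22 was 181 ± 17.0 against 77.5 ± 7.50 and rose by 1.21 (adjusted p = 0.00143). In all, 285 genes differed, 210 higher and 75 lower, and 1629 had an unadjusted p under 0.05.

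Large falls besides Foxo1 were of Krt222, a keratin gene (1.10 ± 0.989 against 11.1 ± 1.39, -2.62), Lmo4, a LIM-domain transcriptional adaptor (6.63 ± 3.38 against 34.1 ± 5.67, -2.29), Gmfg, an actin regulator (9.23 ± 3.17 against 47.02 ± 8.99, -2.26), and BC017612 (5.98 ± 4.42 against 29.97 ± 6.97, -2.30). Tifa was 0.96, 0 and 0 in the Foxo1-deficient libraries against 5.31, 4.62 and 5.76, Mcoln2, an endolysosomal channel, 1.73, 0 and 0 against 5.81, 4.96 and 6.69, and Gdpd3, a phosphodiesterase, 1.99, 0 and 8.75 against 19.2, 25.7 and 17.9. BC024582 was 1.81, 0.38 and 0 against 5.51, 9.67 and 6.64, and Gstt1 was 3.95, 6.77 and 5.55 in DZ. The largest rises were again of Lyz2, S100a9, S100a8, Tyrobp, S100a4, Lyz1, Fcer1g and Plac8, with DZ at no more than 3.18 FPKM in any library, of Beta-s (173 ± 129 against 6.35 ± 2.92, 4.39) and of Hbb-b2, another beta-globin gene (123 ± 77.2 against 9.59 ± 2.07, 3.40). Adjusted p for these genes ran from 1.69e-05 to 0.0475, with no overlap between the groups' libraries, which the naming rule required.

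Of 12 dark zone genes, 4 fell and 0 rose (4 fell adjusted over the list alone), with a median of -0.31 (adjusted p = 1.18e-06, but adjusted p = 0.0944 with an estimated correlation). They were Gcet2, Foxp1, Cxcr4 and Rgs13 (48.9 ± 4.74 against 87.5 ± 10.9). Polh was 28.5 ± 2.71 against 41.1 ± 6.46 (-0.51, adjusted p = 0.23). Of 24 light zone genes, 3 rose and 0 fell (13 rose adjusted over the list alone), with a median of 0.53 (adjusted p = 5.26e-06, but adjusted p = 0.0988 with an estimated correlation). They were Cd86, Cd40 and Id3, an inhibitor of E proteins (60.5 ± 9.81 against 33.1 ± 1.93). Ccnd2 and Bcl2a1d, both lower than in LZ, changed by 0.97 and 0.70 against DZ and did not pass (adjusted p = 0.191 and 0.142). Macrophage markers rose in the same libraries, 7 of 8 tested.

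Of 15 MHC class II genes, 4 rose and 0 fell (9 rose adjusted over the list alone), with a median of 0.53 (adjusted p = 2.02e-08, but adjusted p = 0.169 with an estimated correlation). They were Cd86, Ifi30 (187 ± 6.72 against 83.1 ± 11.6), H2-DMb1 (125 ± 18.9 against 68.8 ± 12.3) and the lysosomal protease Ctss (113 ± 6.15 against 64.1 ± 16.7). Of 23 B cell receptor signalling genes, 5 rose and 1 fell (9 rose and 1 fell adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000947, but adjusted p = 0.383 with an estimated correlation). Inpp5d, an inositol phosphatase that restrains signalling, rose (53.2 ± 5.73 against 29.7 ± 5.83), and Syk, the kinase that carries the receptor signal, fell (64.1 ± 8.23 against 111 ± 12.0). Of 17 T cell help genes, 4 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.76 (adjusted p = 0.000184, but adjusted p = 0.169 with an estimated correlation). Besides Cd86 and Cd40 they were Icosl, the ligand of the T cell receptor ICOS (34.2 ± 2.06 against 13.5 ± 4.10), and Tnfrsf13c, a receptor of the survival factor BAFF (196 ± 15.8 against 97.4 ± 24.9). Of 24 NF-kB and CD40 response genes 1 rose, Cd40 (5 rose adjusted over the list alone), with a median of 0.48 (adjusted p = 0.00395, but adjusted p = 0.223 with an estimated correlation). Class II, Ctss and Icosl are also expressed by macrophages and dendritic cells, whose list had a median change of 2.35.

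Lists of the cell cycle and respiration were tested against DZ. The 30 genes of G2 and M phase held none that passed either way, and their median was -0.17 (adjusted p = 2.2e-05, but adjusted p = 0.169 with an estimated correlation). Of 26 S phase genes 1 fell over all genes and 1 fell adjusted over the list alone, Mcm6, of the replicative helicase (77.5 ± 6.53 against 118 ± 8.65), with a median of -0.32 (adjusted p = 8.89e-07, but adjusted p = 0.192 with an estimated correlation). The Mcm6 call was lost in each of the 9 fits without 1 library (adjusted p up to 0.152), with the replicate number as a block and with only the compared groups in the fit. The 25 oxidative phosphorylation genes held none that passed (2 fell adjusted over the list alone), with a median of -0.31 (adjusted p = 7.24e-06, but adjusted p = 0.191 with an estimated correlation). Sdhb, of succinate dehydrogenase, was 53.9 ± 1.16 against 89.8 ± 13.3 (-0.71, adjusted p = 0.0504). The 17 mTORC1 and amino acid genes held none that passed (4 fell adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0162, but adjusted p = 0.433 with an estimated correlation). It was lost without DZ replicate 2 (adjusted p = 0.081) or Foxo1-deficient replicate 3 (0.101). Of 22 sterol and lipid synthesis genes 1 rose over all genes and 1 rose adjusted over the list alone, Scd1, a fatty acid desaturase (77.3 ± 6.74 against 44.6 ± 1.63), with a median of 0.31 (adjusted p = 0.0373, but adjusted p = 0.289 with an estimated correlation). That call was lost without DZ replicate 1 (adjusted p = 0.0723), DZ replicate 3 (0.0592) or Foxo1-deficient replicate 3 (0.062). The list of Myc targets did not pass (median 0.04, mean -0.02, adjusted p = 0.413), and its median was -0.02 under quantile normalization and -0.14 under median centring. Glycolysis did not pass either (median -0.12, mean 0.03, adjusted p = 0.184), and no gene of these lists passed over all genes or adjusted over the list alone. Of the hypermutation and repair genes 1 rose, Rev1, a translesion polymerase (26.8 ± 3.81 against 12.1 ± 2.42; 1 rose adjusted over the list alone). Its list had a median of 0.01, which was -0.06 and -0.17 under the scalings, and camera placed it below other genes (adjusted p = 0.668). The macrophage and red cell lists rose in the same libraries, with medians of 2.35 and 2.07.

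The all-gene median of the change against DZ was 0.123, and it became 0.001 under quantile normalization and -0.055 under median centring. With it the share of higher genes among the calls went from 73.7% to 60.8% and 44.6%. Relative to these shifts the light zone median was 0.48 and 0.35 and that of the dark zone list -0.43 and -0.49. The count of 285 became 130, 140 and 127 without DZ replicates 1, 2 and 3 and 148, 119 and 149 without Foxo1-deficient replicates 1, 2 and 3. The 210 higher and 75 lower genes became 74 and 74, 74 and 45, and 99 and 50 without Foxo1-deficient replicates 1, 2 and 3, and 142 and 63 over genes with a wild-type mean of at least 1 FPKM. Of 55 calls followed gene by gene, 23 were tested and kept without each of the 9 libraries, among them those of Cd86, Cxcr4, Ptprc, Gcet2, Foxp1, Cd40, Cr2, Cd22, Ifi30, Icosl, Bach2, Lmo4, Gmfg, Krt222, Gstt1 and Tifa. Voom weights kept 188 of the 285 calls. They lost those of Gstt1 and Tifa and of the large rises Lyz2, S100a8, Beta-s, S100a4, Plac8, Lyz1 and Fcer1g. Calls kept in at most 4 of the 9 fits without 1 library included those of Gdpd3 and Ctss (1 of 9 each), Ell2, Slamf7, BC024582, Rgs13, Id3 and Inpp5d. Those of Gdpd3, Ell2 and Slamf7 were also lost with the replicate number as a block, and that of Ell2 under median centring. Without LZ replicates 1, 2 and 3, 4, 5 and 5 of the 55 calls were lost, without DZ replicates 1, 2 and 3, 18, 16 and 16, and without Foxo1-deficient replicates 1, 2 and 3, 16, 16 and 9, with adjusted p up to 0.158.

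Genes that separated the wild-type zones were then followed in Foxo1-deficient cells. Of the 56 genes higher in DZ, 18 (Gcet2 and Cxcr4 among them) differed from DZ and not from LZ, 6 (Polh among them) differed from LZ and not from DZ, and 32 differed from neither. Of the 138 genes higher in LZ, 50 (Cd86, Cd40 and Cr2 among them) differed from DZ only, 30 (Ccnd2, Cd83 and Fcer2a among them) from LZ only, and 58 from neither. By mean value, 36 of the 56 and 80 of the 138 lay nearer LZ. Whether a gene differed more from one zone than from the other was not tested. These genes were chosen on the same LZ and DZ libraries that they are compared with, and macrophage and red cell genes rose in the same Foxo1-deficient libraries.

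Across the 10004 genes, the change of Foxo1-deficient cells against LZ correlated with that of DZ against LZ at Pearson's r = 0.427 (Spearman's rho = 0.420). Genes are not independent replicates, and both changes share the LZ libraries. In 100 simulations with no effect the means were r = 0.4998 and rho = 0.470, both above the values seen, so r and rho show no shared effect. The covariance was 0.131, against 0.0726 in the simulations and 0.0943 from the spread of the LZ libraries alone. Of the genes called in both, 6 were higher in both, against 0.01 in the simulations and 0.386 for independent lists, and 30 were lower in both, against 0.01 and 1.20. The simulations hold almost no calls and independent lists leave out the shared LZ libraries, so neither count shows a shared effect. The covariance was thus above the 0.0943 that sharing the LZ libraries gives on their spread, but no interval was computed for that excess. The LZ libraries were not split between the comparisons, so part of the excess in counts may come from sharing them. Without LZ replicates 1 and 2, r was 0.489 and 0.539.

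**Figure D3:**
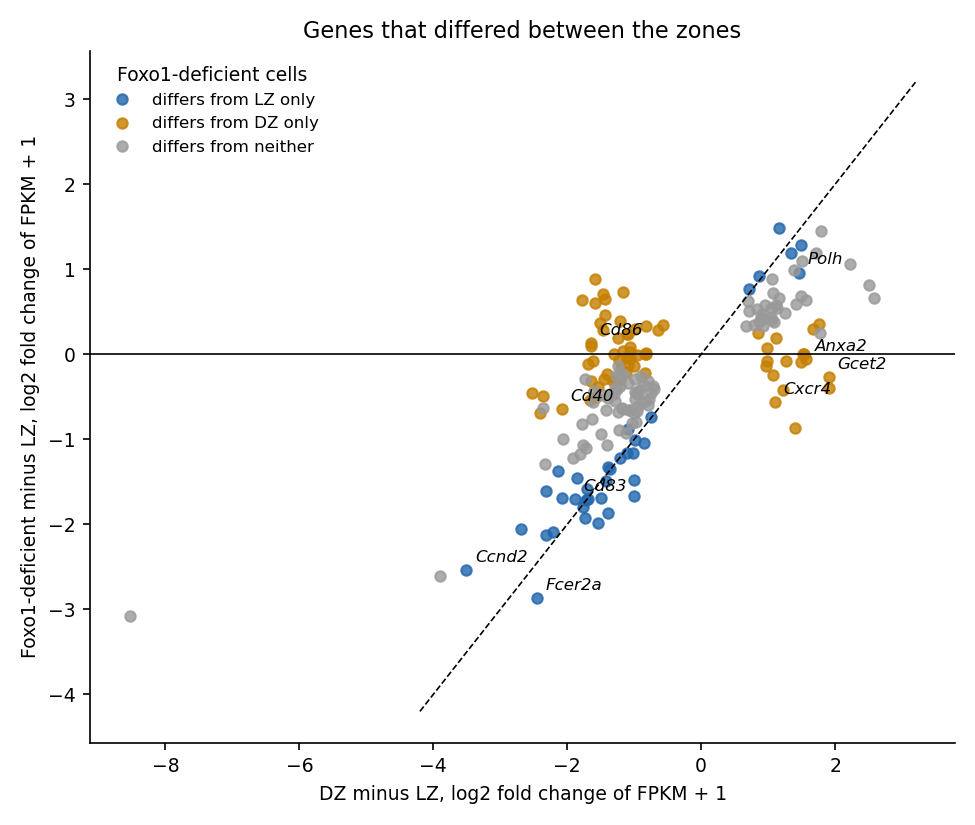
Log2 change of Foxo1-deficient cells against LZ (y axis) and of DZ against LZ (x axis) for the 194 genes that differed between the zones, coloured by whether Foxo1-deficient cells differed from LZ, from DZ or from neither, with a dashed line of equal change. Both axes share the LZ libraries, and the point farthest left is the small RNA gene Mir719, under 0.01 FPKM in the 3 DZ libraries.

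Foxo1-deficient cells differed from LZ and from DZ in the same direction at 71 genes, 54 higher and 17 lower. Simulations with no effect gave 0 higher and 0.02 lower, and independent lists would give 1.45 and 0.652. The simulations hold no effects, and so almost no calls, and independent lists leave out the shared Foxo1-deficient libraries, so part of the 71 may come from sharing them. Genotype and gate change together in both comparisons, so part of the 71 may also come from the gate. The lower genes besides Foxo1 and Gstt1 included Foxp1, Bach2, a repressor of plasma cell differentiation (8.39 ± 3.13 against 20.04 ± 3.63 in LZ and 31.3 ± 3.79 in DZ), Rgs13, and Cd2, an adhesion receptor (9.93 ± 3.34 against 29.98 ± 7.22 and 32.3 ± 9.38). Neurl3, a ubiquitin ligase, was 8.20 ± 3.59 against 21.9 ± 4.43 and 27.4 ± 4.28, Gimap7, a GTPase of lymphocytes, 7.38 ± 3.63 against 25.5 ± 3.70 and 17.6 ± 1.69, and Dus4l, a tRNA-modifying enzyme, 0.25, 0.09 and 0 against 2.03 to 6.84. Krt222, Ddt and Tmem106c were also among the 10 largest falls. Pim1, a survival kinase chosen after its values were seen, was 20.8 ± 5.52 against 44.8 ± 8.23 and 55.3 ± 1.83. The list of T cell markers had 2 tested members, and 1 of them, Cd2, fell in both comparisons over all genes and adjusted over the list alone, while Lat passed in none (0 of 2 passed between the zones).

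The 10 largest rises against both zones were Lyz2, S100a9, S100a8, Tyrobp, S100a4, Plac8, Lyz1, Beta-s, Fcer1g and Ccl6, a chemokine at 7.83, 3.60 and 11.1 in the Foxo1-deficient libraries and listed at 0 in the 6 wild-type libraries. Of the 54 genes higher than both zones, 41 had a wild-type mean under 1 FPKM, 37 lay under 1 FPKM in every wild-type library and 22 were listed at 0 in all 6 wild-type libraries. Chosen after their values were seen, genes with clear wild-type expression included Emid1, an extracellular matrix gene (33.3 ± 8.35 against 6.97 ± 1.37 in LZ and 5.87 ± 1.22 in DZ, 2.09 and 2.31), Laptm5, a lysosomal membrane protein (508 ± 37.3 against 309 ± 22.9 and 311 ± 34.3), and Psap, a lysosomal sphingolipid activator (101 ± 5.21 against 50.0 ± 1.29 and 38.1 ± 8.91). The share of higher genes was 76.1%, and it was 65.3% under quantile normalization and 60.4% under median centring. It was 26.2% without Foxo1-deficient replicate 1 (11 higher and 31 lower), 58.8% and 55.6% without replicates 2 and 3, 48% over genes with a wild-type mean of at least 1 FPKM (12 higher and 13 lower) and 90.2% with no filter (83 higher and 9 lower). The balance of higher and lower genes thus depended on low genes and on single libraries. Voom weights called 65 genes, 25 of them among the 71. The count of 71 became 28, 27 and 32 without LZ replicates 1, 2 and 3, 34, 36 and 42 without DZ replicates 1, 2 and 3, and 42, 17 and 18 without Foxo1-deficient replicates 1, 2 and 3, and was 25 over genes with a wild-type mean of at least 1 FPKM. It was 41 with a pseudocount of 0.1, 36 with a minimum of 5 FPKM and 33 with only the compared groups in the fits. Against LZ, Bach2 and Foxp1 were each called without only 1 of the 9 libraries, with adjusted p up to 0.146 and 0.141. Rgs13 lost a call without LZ replicate 1 or 2, any DZ library, or Foxo1-deficient replicate 1 or 2, with adjusted p up to 0.0736. Cd2 lost one without any LZ library, DZ replicate 1 or 2, or Foxo1-deficient replicate 2 or 3, with adjusted p up to 0.134.

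Genes of B cell identity and of differentiation were followed in the same way. Of 21 germinal center identity genes, 2 rose and 0 fell in DZ against LZ (3 rose and 1 fell adjusted over the list alone), with a median of 0.12 (adjusted p = 0.000367, but adjusted p = 0.342 with an estimated correlation). They were Gcet2 and Pou2af1, a B cell coactivator (404 ± 20.01 against 225 ± 26.3). In Foxo1-deficient cells 2 fell and 0 rose against LZ, Foxp1 and Bach2 (2 rose and 2 fell adjusted over the list alone), while the median was 0.25 and the list stood above other genes (adjusted p = 0.00955, but adjusted p = 0.443 with an estimated correlation). Against DZ 1 rose and 4 fell (4 rose and 4 fell adjusted over the list alone), with a median of 0.12 that was -0.06 under median centring and a mean of -0.11 (adjusted p = 0.622). Ebf1, a B cell lineage factor, rose (36.9 ± 2.32 against 19.1 ± 3.19), and Gcet2, Pou2af1, Foxp1 and Bach2 fell. Macrophage markers had medians of 1.80 and 2.35 in the same libraries.

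Of 12 plasma cell genes 1 rose in DZ against LZ, Igj, the antibody joining chain (200.4 ± 42.7 against 88.8 ± 16.2; 1 rose and 1 fell adjusted over the list alone). The median was -0.02, 0.17 under median centring, and the list did not pass (adjusted p = 0.588). Against LZ 2 rose in Foxo1-deficient cells (3 rose and 1 fell adjusted over the list alone), with a median of 0.21 (adjusted p = 0.00955, but adjusted p = 0.327 with an estimated correlation), a call lost without Foxo1-deficient replicate 2 (adjusted p = 0.176). They were Igj (254 ± 59.6) and Fkbp11, a folding enzyme of secretory cells, at 2.48, 5.21 and 11.5 and listed at 0 in the wild-type libraries. Against DZ 3 rose and 1 fell (3 rose and 1 fell adjusted over the list alone; median 0.28, adjusted p = 0.0613). Besides Fkbp11, Edem1, of the degradation of misfolded proteins (52.2 ± 5.01 against 20.3 ± 4.51), and the elongation factor Ell2 (25.5 ± 3.51 against 13.2 ± 1.41) rose, and the receptor Slamf7 fell (13.7 ± 0.684 against 27.7 ± 3.35). Of 17 naive and memory markers, Fcer2a and Ccr6 fell in DZ against LZ (0 rose and 2 fell adjusted over the list alone; median -0.55, adjusted p = 0.161) and in Foxo1-deficient cells against LZ (1 rose and 4 fell adjusted over the list alone). The median of the latter was -0.42 (adjusted p = 0.00571, but adjusted p = 0.135 with an estimated correlation). Ccr6, a chemokine receptor, was 1.07, 3.13 and 3.11 in LZ and listed at 0 in the other libraries. It was tested in 6 of the 9 fits without 1 library, and its call was kept in 1 of 6 for DZ against LZ (adjusted p up to 0.1197) and in 0 of 6 for Foxo1-deficient cells against LZ (up to 0.126). Both calls were also lost with the replicate number as a block, while those of Fcer2a were kept in every setting. Against DZ 1 fell, Nt5e, an ectonucleotidase (2.09 ± 0.395 against 10.5 ± 2.38; 2 rose and 2 fell adjusted over the list alone; median -0.37, adjusted p = 0.163). The red cell list had medians of 2.05 and 2.07 in the same libraries.

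Markers of other spleen cells were compared as lists. Of 8 tested macrophage and dendritic cell genes, 5 rose against LZ (8 rose adjusted over the list alone) and 7 against DZ (8 rose adjusted over the list alone), with medians of 1.80 and 2.35 (adjusted p = 7.72e-15 and 6.51e-13, but adjusted p = 0.0568 and adjusted p = 0.0631 with an estimated correlation). Csf1r, the receptor of a macrophage growth factor, was 3.42, 4.53 and 6.37 and listed at 0 in the wild-type libraries, and Slc40a1, the iron exporter, was 2.79, 3.71 and 4.42 against at most 0.42. Of 3 tested neutrophil genes, S100a8 and S100a9 rose in both comparisons (2 rose against LZ and 3 rose against DZ adjusted over the list alone), and Cxcr2 passed in neither over all genes. Of 5 tested erythroid and platelet genes, 4 rose against LZ and 4 against DZ (4 and 4 adjusted over the list alone), with medians of 2.05 and 2.07 (adjusted p = 2.32e-08 and 8.89e-07, but adjusted p = 0.0988 and adjusted p = 0.128 with an estimated correlation). Slc4a1, the anion exchanger of red cells, was 3.83, 3.51 and 8.66 against at most 0.06, and Alas2, of heme synthesis, 2.52, 2.48 and 5.10 against at most 0.89. Between the zones none of these 3 lists had a member past the test over all genes, and the first and last gave adjusted p = 0.902 each (1 macrophage gene fell adjusted over the list alone). The median of the first between the zones was 0.00 and turned sign with scaling. Of the 16 tested members of the 3 lists, 12 passed the filter only with the Foxo1-deficient libraries, so the filter favoured members that were high there. The list calls for Foxo1-deficient cells held without each of the 6 wild-type libraries. They were not run without a Foxo1-deficient library, where fewer than 5 members of each list passed the filter. Against LZ, the calls of Alas2 and Slc40a1 were lost without any 1 LZ library (adjusted p up to 0.163 and 0.0682), and that of Alas2 also without any 1 DZ library. Against DZ, that of Alas2 was lost without any 1 DZ library (up to 0.0593). These genes were not tested without a Foxo1-deficient library where they then failed the filter.

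**Figure D4:**
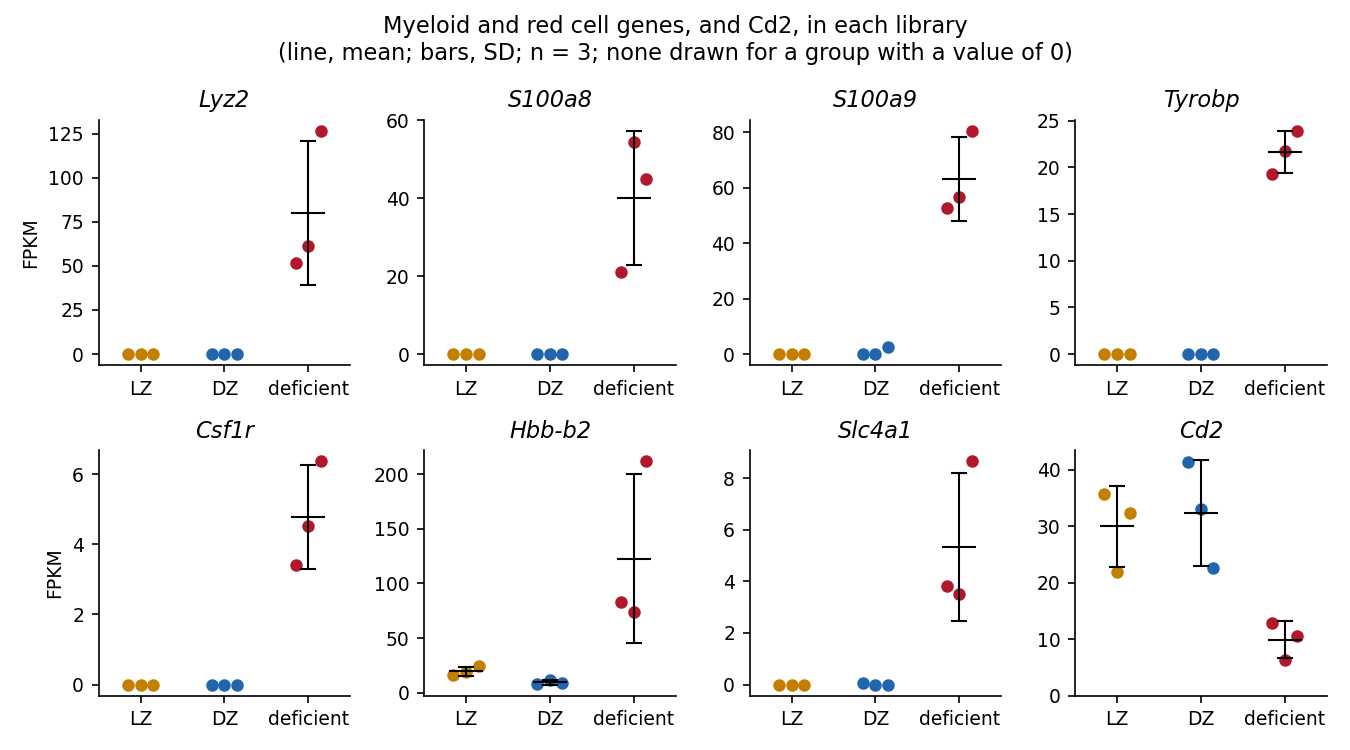
FPKM (y axis, linear, its own scale for each gene) of 7 myeloid and red cell genes and of Cd2, with a point for each library and, for groups with no value of 0, the mean and SD (n = 3). S100a8 is listed at 0 in the 6 wild-type libraries and lies at 21.1 to 54.5 in the Foxo1-deficient libraries.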

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

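The tests on the purity of the sort, on RNA of macrophages, neutrophils and red cells, on DNA linked to one donor strain and on the zeros of Foxo1-deficient replicate 3 were chosen after the result was seen.

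Of 257 symbols left out of the main tests, 84 reached 1 FPKM in a library. The repeated symbols among the 257 were used only in the alternative fit that kept them. In all, 3 of the 257 were higher in each Foxo1-deficient library than in any wild-type library. That share is near the 1 in 84 that chance gives, so the count alone shows no effect. Hba-a1, an alpha-globin gene listed at more than 1 locus, summed to 251.8, 203.5 and 184.4 FPKM in the Foxo1-deficient libraries against at most 7.4 in the wild-type libraries. With Hba-a2, a near-identical copy that makes the separate values uncertain, the sums were 251.8, 203.6 and 576.0 against at most 7.5. Srp54a, of the signal recognition particle, summed to 16.6, 11.7 and 14.8 against at most 11.5, so its lowest Foxo1-deficient value was close to the wild-type range. Groups of 3 libraries were not tested for single libraries that stand apart.

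Genes of macrophages, neutrophils and red cells were higher in the Foxo1-deficient libraries than in both zones, at 11 of the 41 members of their lists with values. A lower purity that brings in all other spleen cells alike would raise T cell genes as well. The T cell list changed by -0.15 (SD 0.09), against 1.54 (SD 0.44) for the macrophage list, so the lists did not rise alike. Of the 18 T cell genes, 5 were listed at 0 in all libraries and 2 were tested, of which 1, Cd2, fell. A small share of T cell RNA could thus go unseen, and the test does not decide on lower purity. RNA of macrophages, neutrophils and red cells was tested by the share of tested members called higher, 68.8% (11 of 16), but 12 of the 16 passed the filter only with the Foxo1-deficient libraries, so the filter fixed most of that share and it decides nothing. Such RNA stays open, and so does expression by the Foxo1-deficient B cells themselves, which was not tested. The B220+ NP+ GL7+ gate is meant to leave out macrophages, neutrophils and red cells, but the purity of the sort was not measured here. Lyz2 reached 127 FPKM, S100a9 80.5 and Beta-s 321, and of the 41 members none is in another list.

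Genes that differed from both zones could come from DNA carried along with the donor's marked loci. Within 10 Mb of Ptprc 1 of 66 tested genes was called, Rgs13, and the odds ratio was 2.2 (interval 0.0541 to 13.1, Fisher p = 0.372), short of the excess set beforehand for such DNA, while 69 genes were called elsewhere. Around Foxo1 0 of 30 tested genes were called (Fisher p = 1). Among the 17 lower genes 1 pair lay within 1 Mb, against a mean of 0.261 over 10000 permutations of the calls (permutation test, p = 0.229). Every Foxo1-deficient library comes from the same donor strain and was sorted without a zone gate. Linkage to that strain, the gate and an effect of Foxo1 thus cannot be told apart.

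Foxo1-deficient replicate 3 listed 230 of 9011 genes with a median of at least 20 implied fragments at exactly 0, and the other libraries 8 to 60. Counting error at the estimated depth gave at most 1 such gene in 10000 simulations, which argues against it as the source of the 230. Calls on genes with such a zero numbered 0 for DZ against LZ, 1 for Foxo1-deficient cells against LZ, 6 against DZ and 1 against both zones. The cause of the zeros in the authors' processing was not tested.

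Regrouping the libraries tested chance. For 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 split, the real one, reached each count: 194 genes for DZ against LZ (highest other 2), 156 for Foxo1-deficient cells against LZ (highest other 1) and 285 against DZ (highest other 2). For changes against both zones 1 of 100 regroupings of the 9 libraries, the real one, gave as many as 71 genes (highest other 32). These regroupings also exchange LZ and DZ libraries, which differ, so they test only whether all 9 libraries are alike. They do not decide whether chance set Foxo1-deficient cells apart from both zones. For the lists 1 of 100, the real one, gave as many as 43 calls. Another regrouping gave 39, so at the preset correlation wrong groups can give nearly as many calls. The number of list calls is thus weak evidence, and 3 of the 43 passed with an estimated correlation.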

How the results depend on the processing

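The voom weights, the fits without small RNA genes or genes with a failed status, with repeated symbols kept, over genes with a wild-type mean of at least 1 FPKM and without genes listed at 0 in 1 library, and the lists without sort genes were chosen after the data were seen.

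Foxo1 stayed below LZ and DZ past the threshold in every setting it was tested in, from -3.39 to -1.78 and from -3.61 to -1.93. Of 7563 values of named results under the alternatives, 6836 were on the same side of the threshold, 570 fell short of it and 157 newly passed it. Changes of direction with a call in the main fit or the alternative numbered 0. Those between uncalled values were not counted apart and are among the 6836. Without 1 library in turn, the counts ran from 73 to 215 for DZ against LZ, 41 to 141 for Foxo1-deficient cells against LZ, 119 to 245 against DZ and 17 to 42 against both zones, with fewer samples in each fit. The correlation of the changes ran from 0.388 to 0.539 in the same fits. For DZ against LZ no filter gave 109 genes, the compared groups alone 122 and voom weights 331. For Foxo1-deficient cells against LZ and against both zones a pseudocount of 0.1 gave 99 and 41, a minimum of 5 FPKM 96 and 36, the compared groups alone 58 and 33, and a wild-type mean of at least 1 FPKM, which removes genes, 74 and 25. With an estimated correlation 3 of the 43 list calls passed, and fry gave 31 calls, 29 of them among the 43. Apart from fewer samples or genes, the cause was not tested. With the replicate number as a block the counts were 161, 137, 221 and 55, and same-number pairs correlated at -0.07 to 0.08, under the threshold of 0.1 set for a pairing. Other pairs correlated at -0.11 to 0.05, and 5 of the 9 libraries correlated best with their own number in each of the other groups. A weak pairing by replicate number thus stays open. Recipients received both kinds of cell, and whether libraries of the same number share mice was not settled here. The main fit has no replicate block, so its p-values leave out such a pairing. The planned count tests were not run, since the files hold FPKM, and the depth is an estimate that limits what can be said of low genes.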

Other observations

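The gene Mir719 and the neighbours of Gstt1 were chosen after the result was seen, and the lists were fixed before.

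Genes of migration, survival and stress have not been described so far. Of 20 chemokine receptor and migration genes, 1 rose and 2 fell in DZ against LZ (1 rose and 3 fell adjusted over the list alone; median -0.21, adjusted p = 0.610), Cxcr4, Ccr6 and S1pr3, a sphingosine phosphate receptor (4.51 ± 0.606 against 16.3 ± 2.70). The Ccr6 calls in both comparisons with LZ were lost with the replicate number as a block. In Foxo1-deficient cells 2 fell against LZ, Ccr6 and Rgs13 (0 rose and 2 fell adjusted over the list alone; median 0.05, camera below other genes, adjusted p = 0.845). Against DZ 1 rose, S1pr3 (12.9 ± 2.16), and 2 fell, Cxcr4 and Rgs13 (4 rose and 2 fell adjusted over the list alone; median 0.24, adjusted p = 0.629). Of 17 apoptosis regulators, 2 fell in DZ against LZ, Bcl2a1b and Bid, a BH3-only protein (29.1 ± 0.832 against 52.8 ± 5.20; 3 fell adjusted over the list alone), with a median of -0.12 that was 0.07 under median centring (adjusted p = 0.645). The Bid call was lost under median centring and without any 1 DZ library or LZ replicate 1 or 2 (adjusted p up to 0.0879). Bcl2a1b fell against LZ (2 fell adjusted over the list alone; median 0.11, mean -0.10, adjusted p = 0.937) and Bid rose against DZ (52.9 ± 6.35; 1 rose adjusted over the list alone; median 0.19, adjusted p = 0.629). Macrophage markers rose in the same Foxo1-deficient libraries.

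Of 24 Foxo targets fixed from general knowledge, Cxcr4 rose and Ccnd2 fell in DZ against LZ (3 rose and 1 fell adjusted over the list alone; median 0.01, mean -0.10, adjusted p = 0.161). In Foxo1-deficient cells 1 fell against LZ, Ccnd2 (1 rose and 1 fell adjusted over the list alone; median 0.29, adjusted p = 0.130), and 1 against DZ, Cxcr4 (1 rose and 1 fell adjusted over the list alone; median 0.27, adjusted p = 0.668). Of 14 stress and dissociation genes, Egr1, an immediate early factor, fell in DZ against LZ (8.03 ± 2.64 against 20.4 ± 2.97; 2 fell adjusted over the list alone; median -0.28, adjusted p = 0.0748). The Egr1 call was lost under quantile normalization and median centring, with the replicate number as a block, and in 7 of the 9 fits without 1 library (adjusted p up to 0.145). The chaperone gene Hspa8 fell in Foxo1-deficient cells against LZ (584 ± 57.2 against 867 ± 58.2; 1 fell adjusted over the list alone), with a median of -0.40 (adjusted p = 0.0475, but adjusted p = 0.191 with an estimated correlation). The Hspa8 call was lost under quantile normalization and in 8 of the 9 fits without 1 library (adjusted p up to 0.138). The list call was lost under quantile normalization (0.0594) and without LZ replicate 1 (0.117) or 3 (0.114), DZ replicate 2 (0.0505) or Foxo1-deficient replicate 1 (0.147), 2 (0.0590) or 3 (0.0549). Against DZ none passed either way, and the median was 0.51 while camera placed the list below other genes (adjusted p = 0.870). Of 15 interferon response genes limma called none either way in any comparison, with medians of -0.06, -0.34 and -0.01 (adjusted p = 0.902, 0.622 and 0.622), the first 0.13 under median centring. Of 2 tested stromal genes, Pecam1, an adhesion molecule, rose in Foxo1-deficient cells against DZ (12.3 ± 3.98 against 4.75 ± 0.471), and none passed in the other comparisons (1 rose and 1 fell between the zones, none against LZ and 1 rose against DZ adjusted over the list alone). The Pecam1 call was lost under quantile normalization and median centring, with the replicate number as a block, and in 8 of the 9 fits without 1 library (adjusted p up to 0.158).

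Near Gstt1 on chromosome 10, Mif, a cytokine gene, fell in Foxo1-deficient cells against LZ (-1.67, adjusted p = 0.000569) and not past the threshold against DZ (-0.66, adjusted p = 0.0560). Gstt2 fell against LZ (-1.87, adjusted p = 0.00306) with -0.48 against DZ (adjusted p = 0.327), and Vpreb3 rose against LZ (1.15, adjusted p = 0.0122) with 0.71 against DZ (adjusted p = 0.0671). Mir719 was 245, 430 and 480 FPKM in LZ, under 0.01 in each DZ library, and 964, 86.1 and 0 in Foxo1-deficient cells.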
